A study of Mus musculus with 4 samples.

How the data were processed

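The series holds 4 libraries of 3' single-cell RNA sequencing with the 10x Genomics Chromium v3.1 chemistry, per the labels' protocols: a gene expression and a hashtag library for each of 2 genotypes. The cells were YFP-positive cells of mouse lung on day 24 after bleomycin. Reads were processed with Cell Ranger 6.0.1 and bcl2fastq against GRCm38, per the submitters' processing notes, and the annotation release is not given in the sources used here. The deposited matrices hold whole-number UMI counts per feature and barcode, not normalized, for 52636 genes and 3 hashtags, and the barcodes had already been filtered by the authors, per the labels. All per-sample columns of the matrices were used.

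A deposited note says that all 3 hashtags occur in every library and that a library pools 3 mice. That 1 hashtag marks 1 mouse is a reading of this note, which it does not state outright. Within a library the hashtags differed in their cluster makeup by more than chance, with a chi-square of 350.7 in WT (5631 cells, highest of 1000 permutations 53.4) and 250.9 in KO (6567 cells, highest 71.7). If a hashtag did not mark a mouse, the tests between pools would measure only a technical spread. The same hashtag number in both libraries marks different mice, so it pairs nothing. Each genotype has 1 library, so genotype, 10x channel and library preparation are confounded, and no batch within a genotype is given.

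Cells were kept with at least 1000 genes and at most 10% mitochondrial UMIs. In WT 516 barcodes had too few genes and 53 too many mitochondrial UMIs (8.75% removed), and in KO 1537 and 44 (17.3%). Hashtag thresholds were set per library and tag at the 99th percentile of a negative binomial fitted to the background cells, after dropping the top 0.5%. Cells above 1 threshold were singlets. Multiplets were removed, 275 in WT (4.63%) and 809 in KO (10.7%). Cells above no threshold, 29 in WT (0.489%) and 185 in KO (2.45%), stayed in the library sums and left the pools. Doublets of 2 cells of the same mouse are not seen by hashtags. Scrublet, the planned second caller, called 2 WT cells (0.0337%) and 0 KO cells and so did not work. As an alternative the cells with the highest Scrublet scores were removed, 130 in WT and 358 in KO, as many as the multiplet rate predicts within a mouse.

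Counts were scaled to the total, log transformed and clustered over both libraries with 2000 highly variable genes, 30 principal components, 15 neighbours and Leiden resolution 0.8, without integration. Clusters were named from 14 marker lists fixed in advance, for adventitial, alveolar, peribronchial, fibrotic and inflammatory fibroblasts, smooth muscle, pericytes, mesothelium, chondrocytes or tendon, proliferating cells, immune, epithelial and endothelial cells and Schwann or glial cells. A cluster needed at least 3 raised markers of a type and stayed unnamed where another type had nearly as many or where its leading genes went against the name. Unnamed clusters were kept among the fibroblasts. Pericyte-like cells and the mixed non-fibroblast cluster were left out.

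For each library the UMIs of all cells of a kind were summed and given as CPM with an exact 95% Poisson interval, shares with an exact 95% binomial interval. These intervals cover counting error only. Log2 ratios of library sums use a pseudocount of 5 CPM. The 20 gene lists began with TGF-beta response, TGF-beta ligands, receptors and SMADs, BMP response, collagens, other matrix, collagen processing, contractile and matrix proteases. Next were chemokines and cytokines, interferon response, antigen presentation, complement, growth factors, Wnt pathway, glycolysis and hypoxia, and lipid and lipofibroblast. The last were secretory pathway, early response and dissociation, proliferation, and senescence and p53. A list is described by the median log2 ratio of members at 5 CPM or more and its percentile among 10000 random lists of the same size and expression.

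KO and WT were compared over the UMI sums of the 6 hashtag pools with edgeR's quasi-likelihood test (TMM factors, the expression filter of edgeR, Benjamini-Hochberg adjustment at 0.05), with 3 pools per genotype. Class comparisons used pools of at least 100 cells. The difference between the classes was tested with each mouse as a block and the interaction of class and genotype. On simulated counts with 100 genes changed 2-fold and 100 changed 4-fold, the test recovered 95% and 99% over all fibroblasts (14979 genes, 12 false calls). It recovered 85% and 95% in the adventitial-like class (11747 genes, 9 false calls) and 69% and 94% in the alveolar-like class (11904 genes, 6 false calls). In the cluster led by Myh11 it recovered 57% and 92% (8833 genes, 5 false calls). For the difference between the classes it recovered 97% of 200 genes changed 4-fold (10132 genes). Every simulated gene of a comparison had the same dispersion, while real genes differ in their spread between pools. The simulation of the class difference used only genes well counted in both classes and no effect of the mouse. Recovery and false calls in the real data may thus differ.

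Named genes were chosen by rule: among genes at 20 CPM or more in a library whose pools did not overlap, the 12 with the highest and the 12 with the lowest log2 ratio over all fibroblasts and 5 each within a class, leaving out predicted, mitochondrial, ribosomal, hemoglobin and sex-linked transcripts. From each list the 4 members with the largest absolute log2 ratio could be named, and Tgfbr2 always. The groups, filters, lists, naming rule, library ratios and the condition for the test between pools were fixed before the data were examined. The condition was that a deposited source says that each hashtag marks a separate mouse. No source used here states this outright, so the condition was not met as worded. It was judged met on the reading of the deposited text given above. If that reading is wrong, the SEs and adjusted p-values between pools do not hold and only the library sums remain. The tests within classes, the cluster led by Myh11 and the test of the difference between classes were added afterwards. So were the gene filter, scaling, DESeq2, block and thinning alternatives of the tests, the removal of the highest Scrublet scores and the other clustering seeds.

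Shares of cells with a UMI were computed after thinning each cell to 3000 UMIs. Alternatives covered the cell filters, the hashtag rule, multiplets, scaling, pseudocount, gene filters, weighting of cells and classes, clustering resolution and seeds, DESeq2, a block for the hashtag number, and leaving out each pool in turn. Weighting the classes equally averaged the log2 ratios of the adventitial-like, alveolar-like and proliferating classes only. The fibrotic-like and the unnamed clusters, the latter 50.5% of KO cells, were left out of it. Gene coordinates are those of the RefSeq annotation of GRCm38. The work used Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, Scanpy 1.11.5, anndata 0.12.19, python-igraph 0.11.9, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16, DESeq2 1.42.0 and limma 3.58.1.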

Results

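The data were single-cell RNA counts of YFP-positive fibroblasts sorted from mouse lungs on day 24 after bleomycin, a drug that injures the lung and is followed by scarring. YFP is a fluorescent reporter protein. One genotype kept Tgfbr2 (WT) and the other had lost it (KO), which per the series title concerns fibroblasts that express the matrix gene Dpt. Each genotype had 1 gene expression library and 1 hashtag library, and in each the cells of 3 mice had been pooled and marked with 3 hashtag antibodies. The WT library held 6504 barcodes with 78734943 gene UMIs and a median of 11051 per barcode. The KO library held 9142 barcodes with 83193356 UMIs and a median of 7828.5. After the filters 5660 WT and 6752 KO cells were used, with medians of 11405.5 and 8475.5 UMIs. Fibroblast clusters held 5625 WT and 6688 KO cells. Their hashtag pools, each read here as 1 mouse, held 1681, 1904 and 2012 cells in WT and 2472, 2442 and 1589 in KO, with 14265233 to 29764675 UMIs per pool. Levels are given as UMI counts scaled to the same total in each pool (CPM), as the mean ± SD of the 3 pools of a genotype, and log2 fold changes of KO over WT are given ± SE with n = 3 pools per genotype.

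Tgfbr2 encodes the TGF-beta receptor subunit that binds the ligand, and lies on chromosome 9 from 116087695 to 116175363 in the GRCm38 annotation (ENSMUSG00000032440). Over all fibroblasts Tgfbr2 stood at 496, 439 and 466 CPM in WT pools 1, 2 and 3 and at 440.2, 419 and 404 CPM in KO pools 1, 2 and 3. The library sums gave 466 CPM in WT (95% Poisson interval 461 to 471, 33354 UMIs) and 421 CPM in KO (416 to 426, 27723 UMIs), a log2 ratio of -0.14. This ratio turned to 0.20 with the classes weighted equally, 0.10 as a mean over cells and 0.10 with every cell thinned to 3000 UMIs. The class weighting covered the adventitial-like, alveolar-like and proliferating classes and left out the fibrotic-like and unnamed clusters. The difference did not pass edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment (log2 fold change -0.19 ± 0.08, adjusted p = 0.0956), with KO pools 2 and 3 below every WT pool and KO pool 1 not. With thinned cells that log2 fold change was 0.018. With a stricter cell filter of 2000 genes and 5% mitochondrial UMIs the same test gave -0.25 with an adjusted p of 0.0371, in a range of 0.0371 to 0.911 over the alternatives run. Within the adventitial-like class the Tgfbr2 level rose in KO, from 456 ± 33.2 to 779.6 ± 51.02 CPM (log2 fold change 0.67 ± 0.10). The pools of the alveolar-like class moved the same way, from 629.6 ± 66.8 to 901 ± 67.5 CPM (log2 fold change 0.40 ± 0.11). All 3 KO pools lay above all 3 WT pools and the edgeR adjusted p was 0.0369 with Benjamini-Hochberg adjustment, but that call was lost when any 1 pool but WT pool 3 was left out, with the hashtag number as a block and with another clustering seed (range over the alternatives 0.00244 to 0.167). In the proliferating class, which was not tested, it was 243 CPM in WT and 149 CPM in KO. The assay counts the 3' ends of transcripts, which need not include the deleted part, so these levels check nothing about the genotype.

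Clustering of all cells gave 16 clusters, of which 9 drew at least 90% of their cells from 1 library and together held 10429 cells (84.0%). Adventitial-like cells, named from markers such as Pi16 and Dpp4, made up 30.6% of WT cells (95% binomial interval 29.4 to 31.8, pools 28.2 to 34.0) and 24.3% of KO cells (23.3 to 25.3, pools 20.9 to 26.8). In KO the name rests mostly on a cluster of 80 WT and 1348 KO cells led by Cxcl13, Csf2rb and Srgn, in which 6 of 13 adventitial markers were raised and 0 were among the 10 leading genes, while Pi16 and Dpp4 led clusters made mostly of WT cells. Alveolar-like cells, named from markers such as Npnt and Ces1d, made up 34.1% of WT (32.8 to 35.3, pools 29.5 to 42.7) and 13.7% of KO (12.9 to 14.6, pools 11.1 to 15.4). These shares hold only for this clustering, since at resolution 1.2 they were 11.9% of WT and 12.9% of KO, at resolution 0.4 the KO share was 1.64%, and with a filter of 500 genes and 20% mitochondrial UMIs the WT share was 22.0%. Fibrotic-like cells, with Cthrc1 among their markers, made up 19.9% of WT (18.9 to 20.99, pools 15.8 to 26.1) and 1.23% of KO (0.980 to 1.52, pools 0.685 to 1.44). Proliferating cells made up 2.30% of WT (1.92 to 2.72, pools 1.35 to 3.56) and 9.32% of KO (8.63 to 10.03, pools 7.06 to 11.6). Clusters that the marker rule left unnamed held 12.5% of WT cells (pools 9.37 to 15.6) and 50.5% of KO cells (pools 48.9 to 52.0), the WT share being 38.2% at resolution 1.2. Pericyte-like cells were 0.3004% and 0.563%, and a mixed non-fibroblast cluster 0.318% and 0.385%, of WT and KO cells. These shares describe the clusters of these libraries and are not compared between genotypes, because the genes that define the clusters themselves differed between the genotypes.

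Over all fibroblasts, most genes of the TGF-beta response and most collagen and other matrix genes fell in KO, while 14 of 17 tested glycolysis and hypoxia genes, all 16 proliferation genes and 12 of 23 chemokines and cytokines rose. The series compared the genotypes to learn what removing Tgfbr2 does to lung fibroblasts in fibrosis. Ctgf, a secreted matricellular protein and standard target of TGF-beta, fell from 498 ± 66.9 to 29.2 ± 7.98 CPM, a log2 fold change of -4.13 ± 0.23. Eln, which encodes elastin, fell from 3303 ± 599.9 to 218 ± 60.3 CPM, a log2 fold change of -3.96 ± 0.24, and Mfap4, a microfibril-associated protein, fell from 1313 ± 359 to 63.0 ± 31.0 CPM, a log2 fold change of -4.42 ± 0.39. Igf1, the insulin-like growth factor, fell from 1081 ± 313 to 70.8 ± 11.1 CPM, a log2 fold change of -3.96 ± 0.25. Cck, which encodes the peptide cholecystokinin, rose from 9.40 ± 2.75 to 616 ± 41.2 CPM, a log2 fold change of 5.97 ± 0.23, and Cxcl13, a B cell chemokine, rose from 116 ± 53.6 to 1154 ± 69.4 CPM, a log2 fold change of 3.27 ± 0.33.

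The 12 genes with the lowest log2 ratio among those whose pools did not overlap were Igfbp2, Mfap4, Ctgf, Igf1, Eln, Cilp, Aspn, Nrep, Bpgm, Itgbl1, Adamtsl2 and Ltbp2. All 12 passed edgeR's quasi-likelihood test, the highest Benjamini-Hochberg adjusted p being 0.000490 for Igfbp2, and by this choice all 3 KO pools lay below all 3 WT pools. Igfbp2, a carrier of insulin-like growth factors, had 148 ± 74.5 CPM in WT and 2.29 ± 2.40 in KO. Cilp, a cartilage intermediate layer protein, had 152 ± 24.7 CPM in WT and 6.98 ± 2.57 in KO, and Itgbl1 79.7 ± 9.99 CPM in WT and 2.42 ± 0.734 in KO. Aspn, a small proteoglycan, had 282 ± 116 CPM in WT and 18.0 ± 4.33 in KO, and Ltbp2, a latent TGF-beta binding protein, 688 ± 153 CPM in WT and 64.7 ± 15.1 in KO. The log2 fold changes were -4.03 ± 0.23 for Nrep, -4.08 ± 0.18 for Bpgm and -5.31 ± 0.35 for Adamtsl2. The 12 at the other end were Cck, Retnla, Nrn1, Sema3a, Hmga2, Slc14a1, Stc1, Ereg, Slpi, Ptges, Cxcl13 and Il1rl1. All 12 passed the same test, the highest adjusted p being 0.00463 for Slpi, and by the same choice all 3 KO pools lay above all 3 WT pools. Retnla, Stc1 and Ereg were among the 10 leading genes of an unnamed cluster of 1 WT and 1593 KO cells. Il1rl1, Slc14a1, Cck, Nrn1, Hmga2 and Slpi were among those of another, of 2 WT and 1201 KO cells. Their rise over all fibroblasts thus also holds these clusters, which cannot be told from the KO library. Retnla, a resistin-like protein, had 0.611 ± 0.124 CPM in WT and 257 ± 144 in KO. Nrn1, a neuritin, had 1.36 ± 0.507 CPM in WT and 194 ± 70.8 in KO, and Sema3a, an axon guidance protein, 9.63 ± 4.71 CPM in WT and 363 ± 43.6 in KO. Stc1, a stanniocalcin, had 9.36 ± 3.30 CPM in WT and 176 ± 18.6 in KO, and Ptges, a prostaglandin E synthase, 47.7 ± 9.45 CPM in WT and 469 ± 87.4 in KO. Ereg, a ligand of the EGF receptor, had 43.0 ± 24.9 CPM in WT and 500.1 ± 111 in KO, and Il1rl1, the receptor of interleukin 33, 3.11 ± 1.27 CPM in WT and 64.7 ± 18.0 in KO. Hmga2 had 4.05 ± 5.32 CPM in WT and 132 ± 59.1 in KO and Slpi, a protease inhibitor, 32.9 ± 31.3 CPM in WT and 382 ± 39.1 in KO. Slc14a1, a urea transporter, was close to the detection limit in WT, at 0.0419 CPM (95% Poisson interval 0.00864 to 0.122), and stood at 65.8 CPM (63.9 to 67.8) in KO.

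**Figure D1:**
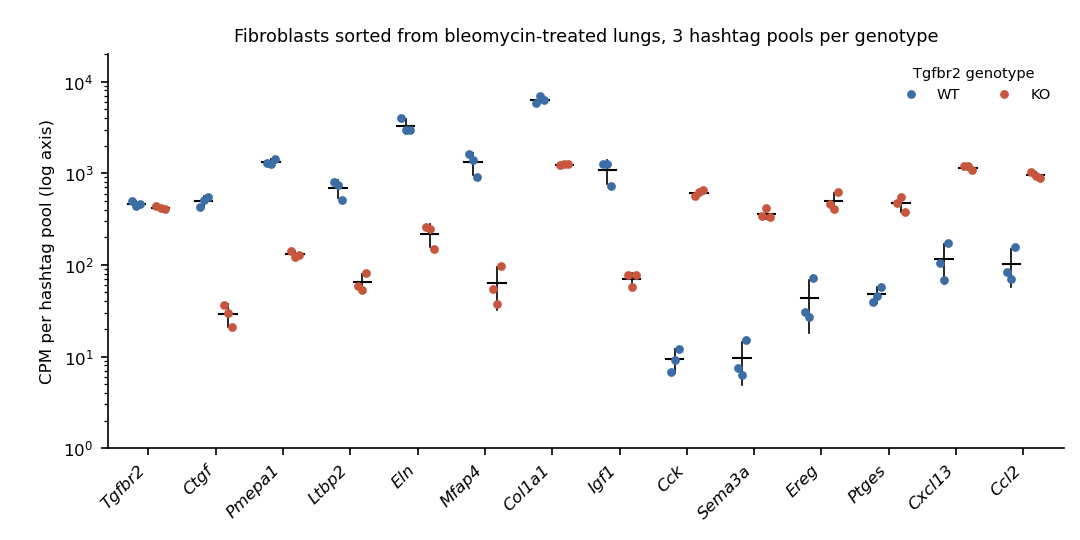
Level of 14 genes in each hashtag pool of fibroblasts, in CPM on a log axis, with the mean and SD of the 3 pools of each genotype. Ctgf averaged 498 CPM in WT and 29.2 in KO, Cck 9.40 and 616, and Tgfbr2 467 and 421.

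Of the 16 tested genes of the TGF-beta response list, 2 rose, 11 fell and 3 did not pass edgeR's test, with 2 up and 11 down adjusted over the list alone. The list had a median log2 library ratio of -0.78, lower than all of 10000 random lists of its size matched on expression. The collagen, other matrix, collagen processing, interferon response and Wnt pathway lists also lay below all of theirs. The chemokine, glycolysis and proliferation lists lay above all of theirs. Random lists drew genes singly, so they do not hold how the genes of a list move together. The ranks rest on 1 library sum per genotype and hold no spread between pools. Pmepa1, an inhibitor of TGF-beta signaling that the pathway itself induces, fell from 1341 ± 85.2 to 131 ± 9.96 CPM, a log2 fold change of -3.39 ± 0.11. Nox4, an NADPH oxidase, fell from 131 ± 18.7 to 28.5 ± 4.80 CPM, a log2 fold change of -2.23 ± 0.14. The members that rose were Klf10, named here after its value was seen, and Cdkn2b, a cell cycle inhibitor, which rose from 19.7 ± 2.80 to 38.9 ± 3.59 CPM. Without WT pool 3, 4 members rose. Of the 15 TGF-beta ligands, receptors and SMADs, 3 rose, 7 fell and 5 did not pass (3 up and 8 down adjusted over the list alone; median log2 ratio -0.30, or -0.11 with the classes weighted equally). Only 1 of them rose without WT pool 1, WT pool 2 or KO pool 1. Tgfb3, a TGF-beta ligand, fell from 135 ± 49.5 to 25.8 ± 2.99 CPM, a log2 fold change of -2.43 ± 0.27, and the ligand Tgfb1 had a log2 fold change of -1.45 ± 0.17. Ltbp4, which binds latent TGF-beta, had -1.80 ± 0.18, and Smad3, a signal transducer of the receptor, rose by a log2 fold change of 1.05 ± 0.08. In the BMP response list 1 of 8 tested members rose and 2 fell, with the same numbers adjusted over the list alone. The number that fell was 0 without WT pool 1 or KO pool 2 and 1 without WT pool 2, KO pool 1 or KO pool 3. Id1, a target of BMP signaling, rose from 47.5 ± 1.44 to 127 ± 22.9 CPM, a log2 fold change of 1.37 ± 0.12. The median log2 ratio of the BMP list was 0.05, against a mean of 0.20. It changed sign to -0.11 without WT pool 3 and to -0.0118 without KO pool 3, and was 0.14 without WT pool 1, 0.11 without WT pool 2 and 0.14 without KO pool 1.

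Of 19 tested collagen genes, 1 rose, 16 fell and 2 did not pass the test, with the same numbers adjusted over the list alone, and the median log2 ratio was -1.51. Col1a1, the main fibrillar collagen chain, fell from 6364 ± 542 to 1243 ± 23.6 CPM, a log2 fold change of -2.40 ± 0.12. Col8a1 fell from 118 ± 29.1 to 11.2 ± 2.56 CPM, a log2 fold change of -3.46 ± 0.25, Col15a1 from 171 ± 4.26 to 35.9 ± 10.1 CPM, a log2 fold change of -2.30 ± 0.18, and Col11a1 from 30.9 ± 15.1 to 0.833 ± 0.578 CPM. Of 23 other matrix genes, 0 rose, 16 fell and 7 did not pass (2 up and 17 down adjusted over the list alone; median log2 ratio -1.59). Without KO pool 2, 1 of these rose. Besides Eln, Mfap4 and Cilp, Postn, the matricellular protein periostin, fell from 486 ± 42.6 to 83.5 ± 63.7 CPM, a log2 fold change of -2.59 ± 0.48. Of 18 tested genes that modify or crosslink collagen, 1 rose, 12 fell and 5 did not pass (1 up and 13 down adjusted over the list alone; median log2 ratio -0.67), and 2 rose without WT pool 3. Lox, the lysyl oxidase that crosslinks collagen and elastin, fell from 349 ± 103 to 74.1 ± 8.95 CPM, a log2 fold change of -2.28 ± 0.22. Plod2, a lysyl hydroxylase, had a log2 fold change of -1.57 ± 0.08 and P4ha3, a prolyl hydroxylase subunit, of -2.32 ± 0.12. Of 15 contractile genes, 3 rose, 9 fell and 3 did not pass, with the same numbers adjusted over the list alone and a median log2 ratio of -0.33. No contractile gene rose without WT pool 1, WT pool 2, KO pool 1 or KO pool 2. Tagln, an actin-binding protein of smooth muscle and myofibroblasts, fell from 1423 ± 94.6 to 416 ± 104 CPM, a log2 fold change of -1.81 ± 0.19. Cnn1 and Lmod1, both of smooth muscle, had log2 fold changes of -2.04 ± 0.32 and -2.23 ± 0.40, and the myosin light chain Myl9 of -1.48 ± 0.18. The fibroblasts counted here include an unnamed cluster of 474 WT and 7 KO cells, with Cnn1 and Lmod1 among its leading genes. It had 7 of 7 smooth muscle markers raised, and another of 2 WT and 441 KO cells had 5 of 7. Of 14 contractile genes, 2 rose and 2 fell in the adventitial-like class, and 1 rose and 10 fell in the alveolar-like class. Of 17 tested matrix proteases and inhibitors, 4 rose, 7 fell and 6 did not pass (5 up and 8 down adjusted over the list alone; median log2 ratio -0.27), and 2 rose without WT pool 1 or WT pool 2 and 1 without KO pool 2. Mmp2 and Ctsk fell by log2 fold changes of -1.57 ± 0.11 and -1.46 ± 0.13, Adamts12 had -1.46 ± 0.20, and Mmp19 rose from 46.0 ± 3.08 to 168 ± 21.4 CPM, a log2 fold change of 1.83 ± 0.11.

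**Figure D2:**
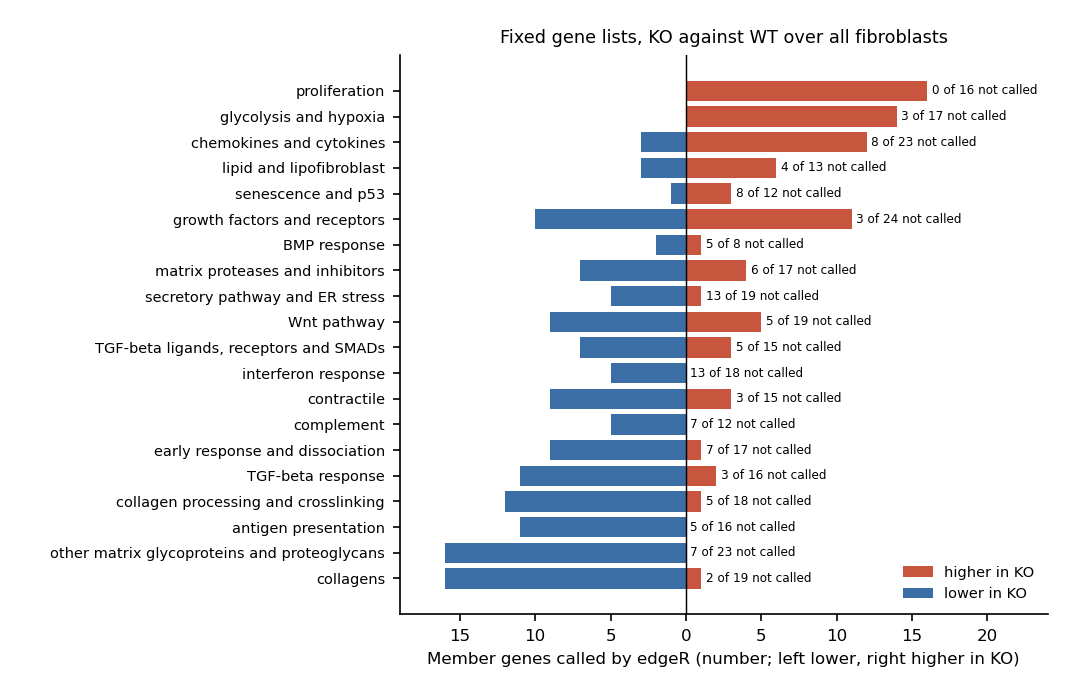
Number of tested members of each gene list that edgeR called higher (right) or lower (left) in KO over all fibroblasts. Among the collagens 1 member was higher and 16 were lower, and among the proliferation genes 16 were higher and 0 lower.

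Of 23 tested chemokine and cytokine genes, 12 rose, 3 fell and 8 did not pass (12 up and 3 down adjusted over the list alone), and the median log2 ratio of 0.71 lay above all of 10000 random lists. The number that rose was 7 without WT pool 1, and the number that fell 1 without WT pool 1 or KO pool 1. Besides Cxcl13, Ccl2, which attracts monocytes, rose from 103 ± 45.5 to 953 ± 80.0 CPM, a log2 fold change of 3.16 ± 0.30, and Cxcl2, which attracts neutrophils, rose from 5.998 ± 1.32 to 66.7 ± 15.1 CPM, a log2 fold change of 3.43 ± 0.22. Ccl2 and Cxcl2 were among the 10 leading genes of the unnamed cluster of 2 WT and 1201 KO cells. Of 18 interferon response genes, 0 rose, 5 fell and 13 did not pass, with the same numbers adjusted over the list alone and a median log2 ratio of -0.43 (-0.28 without KO pool 2). The number that fell was 2 without WT pool 1 or WT pool 2, 1 without KO pool 1 or KO pool 2 and 11 without KO pool 3. Ifit3 fell from 51.3 ± 13.3 to 25.6 ± 9.26 CPM, a log2 fold change of -1.06 ± 0.27. That call was lost without WT pool 2, KO pool 1 or KO pool 2, and adjusted p over the alternatives of edgeR's test with Benjamini-Hochberg adjustment ran from 0.000186 to 0.0718. Bst2 and Isg15 did not pass, with 225 ± 52.3 CPM in WT and 129 ± 75.8 in KO and with 106 ± 32.0 CPM in WT and 73.4 ± 47.0 in KO, but both passed without KO pool 3 (log2 fold changes -1.43 and -1.23), and Bst2 also with no filter on low genes. Other left-out pools brought both closer to 0, Bst2 to -0.55 without KO pool 2, and Isg15 to -0.27 without KO pool 2, -0.32 without WT pool 2 and -0.38 without KO pool 1, from -0.84 and -0.58. By class, 3 of 18 interferon response genes fell in the adventitial-like (median log2 ratio -0.02) and 8 of 18 in the alveolar-like class (-0.53), and 0 rose in either. In the cluster led by Myh11, 2 of 17 rose and 0 fell (1 and 0 adjusted over the list alone; median log2 ratio 0.05). Over all fibroblasts, 0 of 16 tested antigen presentation genes rose, 11 fell and 5 did not pass (0 up and 13 down adjusted over the list alone; median log2 ratio -0.67), and without KO pool 2, 1 rose and 7 fell. H2-D1, a class I histocompatibility molecule, fell from 761 ± 124 to 481 ± 79.8 CPM, a log2 fold change of -0.70 ± 0.16, and Tapbp, which loads peptides on it, had a log2 fold change of -0.74 ± 0.14. By class, 4 of 16 antigen presentation genes fell in the adventitial-like (7 adjusted over the list alone; median log2 ratio -0.28) and 12 of 16 in the alveolar-like class, and 0 rose in either. In the cluster led by Myh11, 0 of 11 rose or fell (median log2 ratio 0.16). Over all fibroblasts, 0 of 12 tested complement genes rose, 5 fell and 7 did not pass, with the same numbers adjusted over the list alone and a median log2 ratio of -0.32. That median was -0.18 without KO pool 2 and -0.18 with the classes weighted equally. It was 0.14 in the adventitial-like class, where 1 of 10 rose and 3 fell (2 and 3 adjusted over the list alone; mean log2 ratio -0.29). In the alveolar-like class it was 0.27, but the mean log2 ratio was 0.00592, and 0 of 12 rose and 4 fell (2 and 4 adjusted over the list alone). Cd55, a regulator of complement, had a log2 fold change of -2.03 ± 0.25, C7 of -1.42 ± 0.18 and C4b of -0.74 ± 0.17. Of 24 growth factors and receptors, 11 rose, 10 fell and 3 did not pass (11 up and 12 down adjusted over the list alone), with a median log2 ratio of 0.02 but a mean of -0.18. The median was 0.38 over members at 20 CPM or more, and it was -0.0019 without WT pool 1, -0.00749 without KO pool 1, -0.00238 without KO pool 3, 0.0913 without WT pool 3 and 0.0659 without KO pool 2. Without WT pool 1, 6 members rose. Areg, a ligand of the EGF receptor, rose from 5.82 ± 5.01 to 56.5 ± 29.2 CPM, a log2 fold change of 3.16 ± 0.61. Of 19 Wnt pathway genes, 5 rose, 9 fell and 5 did not pass (6 up and 9 down adjusted over the list alone; median log2 ratio -0.49, or -0.17 with the classes weighted equally and -0.76 over members at 20 CPM or more). Without WT pool 2, 3 rose. Wisp2 and Wisp1, secreted relatives of Ctgf, fell by log2 fold changes of -3.35 ± 0.14 and -3.09 ± 0.32, and Dkk2, a secreted Wnt regulator, had -2.82 ± 0.32. Notum, an enzyme that inactivates Wnt proteins, rose from 16.7 ± 4.12 to 106 ± 27.1 CPM, a log2 fold change of 2.62 ± 0.23.

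Of 17 tested glycolysis and hypoxia genes, 14 rose, 0 fell and 3 did not pass (15 up and 0 down adjusted over the list alone; median log2 ratio 0.70, or 0.39 with the classes weighted equally). Without WT pool 2, 9 rose. Within the classes 8 of 16 rose in the adventitial-like and 3 of 15 in the alveolar-like class, and 0 fell in either (9 and 3 adjusted over the list alone). The glycolytic enzymes Eno1, Pkm and Ldha rose by log2 fold changes of 1.43 ± 0.22, 1.02 ± 0.21 and 0.96 ± 0.14. All 16 proliferation genes rose, also adjusted over the list alone. The median log2 ratio of that list was 1.15, and 0.00938 with the classes weighted equally, so that proliferating cells, 9.32% of KO and 2.30% of WT cells, counted no more in KO than in WT. Cenpf, a kinetochore protein, rose from 25.1 ± 9.18 to 68.4 ± 10.3 CPM, a log2 fold change of 1.41 ± 0.26, and Ccnb1, a mitotic cyclin, and Hmgb2 had log2 fold changes of 1.75 ± 0.33 and 1.30 ± 0.17. Of 13 tested lipid and lipofibroblast genes, 6 rose, 3 fell and 4 did not pass, with the same numbers adjusted over the list alone and a median log2 ratio of 0.30. The number that rose was 3 without WT pool 1 or WT pool 2, and the number that fell 1 without WT pool 1, WT pool 2, KO pool 1 or KO pool 2. Lpl, a lipoprotein lipase, fell from 572 ± 72.6 to 102 ± 45.9 CPM, a log2 fold change of -2.53 ± 0.30. Of 19 tested secretory pathway genes, 1 rose, 5 fell and 13 did not pass, with the same numbers adjusted over the list alone and a median log2 ratio of -0.12. That median turned to 0.0676 without KO pool 2 and was -0.0113 without WT pool 2, -0.20 without WT pool 3, -0.21 without KO pool 3 and -0.0707 with the classes weighted equally. The number that fell was 3 without WT pool 1 or WT pool 2 and 2 without KO pool 1 or KO pool 2, and 2 rose without WT pool 3. Kdelr3, a retrieval receptor of the endoplasmic reticulum, had a log2 fold change of -1.14 ± 0.07, the stress gene Ddit3 of -0.72 ± 0.15 and Xbp1 of 0.49 ± 0.10. Of 17 early response and dissociation genes, 1 rose, 9 fell and 7 did not pass (1 up and 10 down adjusted over the list alone; median log2 ratio -0.60). None of them rose without WT pool 1, WT pool 2 or KO pool 1. The list was also set for tissue dissociation, which 1 library per genotype cannot separate from the genotype. Egr1, Fosb and Klf2 fell by log2 fold changes of -0.78 ± 0.16, -0.79 ± 0.17 and -0.88 ± 0.09. Of 12 senescence and p53 genes, 3 rose, 1 fell and 8 did not pass, with the same numbers adjusted over the list alone. Cdkn2a, a cell cycle inhibitor, rose from 12.4 ± 4.19 to 77.1 ± 15.6 CPM, a log2 fold change of 2.57 ± 0.27. The median log2 library ratio of the senescence list was 0.03 and its median edgeR log2 fold change -0.00300, while its mean log2 ratio was 0.21. Left-out pools moved this median from -0.00142 without WT pool 3 to 0.11 without WT pool 2, with 0.0137 without WT pool 1, 0.0921 without KO pool 1, 0.0146 without KO pool 2 and 0.00439 without KO pool 3. The number that fell was 0 without WT pool 1, WT pool 2, KO pool 1 or KO pool 2 and 2 without WT pool 3 or KO pool 3.

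Among marker lists of fibroblast types, 10 of 16 tested adventitial markers fell and 0 rose (11 adjusted over the list alone; median log2 ratio -0.71). Of 12 alveolar markers 2 rose and 5 fell (2 and 7 adjusted over the list alone; -0.54). All 6 peribronchial markers fell, also adjusted over the list alone (median log2 ratio -1.88). Of 10 fibrotic markers 2 rose and 7 fell, with the same numbers adjusted over the list alone (-1.73). Of 10 inflammatory markers 6 rose and 0 fell (7 and 0 adjusted over the list alone; 1.02), and all 9 proliferating markers rose, also adjusted over the list alone (1.25). Markers of other cell types were called in these numbers, the same over the list alone. Of 8 smooth muscle markers 1 rose and 5 fell (median log2 ratio -1.57), of 7 pericyte markers 2 rose and 4 fell (-0.53), of 5 chondrocyte or tendon markers 1 rose and 4 fell (-2.004), and of 4 mesothelial markers 2 rose and 1 fell (-0.14, against a median edgeR log2 fold change of 1.38). Of 6 immune markers 1 rose and 5 fell (-1.29, against a mean of -0.40), and of 7 epithelial markers 0 rose and 1 fell (-1.01). Of 4 endothelial markers 1 rose and 0 fell (0.07), and of 3 Schwann or glial markers 0 rose and 2 fell (-0.67). The medians rest only on members at 5 CPM or more. These were 4 chondrocyte or tendon, 3 immune, 2 each of mesothelial, epithelial and endothelial, and 1 Schwann or glial marker.

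Across all genes, edgeR's quasi-likelihood test called 3151 genes higher and 2881 lower in KO of 15173 tested, 870 and 1234 of them by at least 2-fold. The number higher was 1911 without WT pool 1, 1836 without WT pool 2 and 1888 with every cell thinned to 3000 UMIs. By the library ratio alone, 227 genes at 20 CPM or more were at least 2-fold higher and 299 at least 2-fold lower with pools that did not overlap. The numbers were 125 and 179 with the adventitial-like, alveolar-like and proliferating classes weighted equally and the other clusters left out. Pools did not overlap for 4234 of 6650 genes (63.7%), where chance gives 10% for 3 pools against 3. Each genotype had 1 library and 1 10x channel, so genotype and channel cannot be told apart by the design.

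Shares of fibroblasts with at least 1 UMI were compared after thinning each cell to 3000 UMIs, which left out 49 WT and 95 KO cells. Cthrc1, a marker of fibrotic fibroblasts, was seen in 21.3% of WT (95% interval 20.2 to 22.3, pools 17.8, 22.3 and 23.2) and 6.28% of KO cells (5.71 to 6.89, pools 5.88, 5.70 and 7.17). Postn was seen in 32.1% of WT (95% interval 30.9 to 33.3, pools 30.3, 34.2 and 31.6) and 7.49% of KO cells (6.87 to 8.15, pools 6.75, 5.53 and 11.9). Pi16, an adventitial marker, was seen in 18.4% of WT (95% interval 17.4 to 19.4, pools 18.5, 20.9 and 15.8) and 4.29% of KO cells (3.82 to 4.81, pools 5.22, 3.47 and 4.04). Lrrc15, a myofibroblast marker, was seen in 1.49% of WT (95% interval 1.19 to 1.84, pools 1.02, 1.69 and 1.65) and 0.0910% of KO cells (0.0334 to 0.198, pools 0.0411, 0.165 and 0). Saa3, an acute phase protein, was seen in 7.75% of WT (95% interval 7.06 to 8.48, pools 6.80, 5.13 and 10.9) and 29.2% of KO cells (28.1 to 30.3, pools 30.8, 29.6 and 26.7). Lcn2, which encodes lipocalin, was seen in 5.92% of WT (95% interval 5.31 to 6.57, pools 4.15, 1.96 and 11.0) and 28.9% of KO cells (27.8 to 30.1, pools 28.9, 31.3 and 26.2). The thinned shares of WT and KO cells were 45.1% and 43.1% for Acta2, 40.8% and 36.2% for Tnc, 35.7% and 37.4% for Npnt, 67.1% and 63.5% for Tgfbr2, 2.46% and 6.37% for Mki67 and 0.448% and 0.212% for Dpt. For Npnt the direction turned with at least 2 UMIs, to 20.5% and 19.7%, and for Dpt with cells thinned to 1500 UMIs, to 0.107% and 0.120%, with no cell of either genotype at 2 UMIs of Dpt. Without thinning the shares were 33.8% and 14.997% for Cthrc1, 46.0% and 10.9% for Postn, 26.3% and 6.82% for Pi16, 3.88% and 0.284% for Lrrc15. They were 11.9% and 37.5% for Saa3, 10.3% and 40.8% for Lcn2, 62.4% and 56.8% for Acta2, 60.8% and 55.1% for Tnc, 54.7% and 56.6% for Npnt, 92.6% and 89.6% for Tgfbr2, 3.93% and 10.3% for Mki67 and 1.58% and 0.478% for Dpt. In the mixed non-fibroblast cluster, 18 WT and 22 KO cells after thinning, the shares of WT and KO cells with a UMI were 22.2% and 4.55% for Postn, 5.56% and 4.55% for Pi16, 22.2% and 4.55% for Saa3, 11.1% and 4.55% for Lcn2. They were 11.1% and 4.55% for Acta2, 16.7% and 9.09% for Tnc, 27.8% and 27.3% for Npnt, 55.6% and 45.5% for Tgfbr2 and 11.1% and 9.09% for Mki67. No such cell had a UMI of Cthrc1, Lrrc15 or Dpt, which allows shares of up to 18.5% in WT and 15.4% in KO. Median depth was 11416 UMIs per WT and 8490.5 per KO fibroblast, and 8576.5 and 6428.5 in the non-fibroblast cells. The cluster holds immune and epithelial cells, led by Igkc and Sftpc, which can express Mki67, Saa3, Lcn2, Tgfbr2 and Npnt themselves, so it sets no background for these genes. Among the other genes, the shares of Acta2 in both genotypes lay above its upper 95% limits (34.7% and 22.8%), as did those of Cthrc1 in WT (limit 18.5%) and of Tnc in KO (limit 29.2%). For Postn, Pi16, Lrrc15, Dpt, Cthrc1 in KO and Tnc in WT, free RNA is not excluded at this number of cells.

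Within the adventitial-like class, 15 of 18 tested collagens fell and 12 of 22 chemokines and cytokines rose. The WT cells of this class came mostly from a cluster led by Pi16 and Col14a1 (1184 of 1733) and the KO cells from a cluster led by Cxcl13 (1348 of 1639), so that the class mixes different clusters in the genotypes. Its own markers moved too, as 10 of 16 adventitial markers fell and 1 rose (13 and 3 adjusted over the list alone; median log2 ratio -0.37), while 9 of 10 inflammatory fibroblast markers rose and 0 fell (1.29) and 4 of 9 fibrotic markers fell and 1 rose (-0.86), both also over the list alone. Mfap4 fell from 1505 ± 388 to 29.1 ± 4.596 CPM, a log2 fold change of -5.78 ± 0.23, and Cilp fell from 268 ± 98.4 to 8.62 ± 6.71 CPM, a log2 fold change of -5.05 ± 0.46. Cthrc1, a secreted collagen triple helix protein, fell from 206 ± 78.3 to 15.4 ± 4.13 CPM, a log2 fold change of -3.85 ± 0.30. Ctgf fell from 351 ± 125 to 34.0 ± 6.17 CPM, a log2 fold change of -3.47 ± 0.26, and Itgbl1 had -4.33 ± 0.20. Cxcl13 rose from 442 ± 252 to 5107 ± 991 CPM, a log2 fold change of 3.42 ± 0.37. Aqp1, a water channel, rose from 41.5 ± 20.8 to 461 ± 97.2 CPM, a log2 fold change of 3.36 ± 0.30, and Ifitm1 from 111 ± 20.2 to 951 ± 47.3 CPM, a log2 fold change of 2.995 ± 0.14. Bpifa2 rose from 3.27 ± 0.835 to 113 ± 17.7 CPM and Slco2a1, a prostaglandin transporter, from 4.29 ± 2.97 to 62.3 ± 14.6 CPM. The highest adjusted p of these 10 genes was 0.000208 for Cxcl13 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The genes had been chosen among those whose pools did not overlap, so all 3 KO pools lay on one side of all 3 WT pools.

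Of 16 TGF-beta response genes in this class, 0 rose, 7 fell and 9 did not pass (1 up and 10 down adjusted over the list alone), with Pmepa1 at -2.56 ± 0.10. Of 18 collagens, 0 rose, 15 fell and 3 did not pass (1 up and 16 down adjusted over the list alone), with Col1a1 at -2.03 ± 0.16 and Col8a1 at -3.27 ± 0.38. Of 23 other matrix genes, 1 rose, 13 fell and 9 did not pass (1 up and 14 down adjusted over the list alone). Of 14 contractile genes, 2 rose, 2 fell and 10 did not pass (3 up and 4 down adjusted over the list alone), with a median log2 ratio of 0.09 but a median edgeR log2 fold change of -0.00783. Flna, a filamin, was at 0.75 ± 0.09. Tagln did not pass, at 232 ± 169 CPM in WT and 144 ± 7.75 in KO (log2 fold change -0.80, and -0.013 without WT pool 3), but passed with no filter on low genes. Of 22 chemokines and cytokines, 12 rose, 1 fell and 9 did not pass (15 up and 2 down adjusted over the list alone), with Lcn2 at 2.93 ± 0.57 (4.56 without WT pool 3). Of 18 Wnt pathway genes, 3 rose, 8 fell and 7 did not pass (3 up and 9 down adjusted over the list alone), with Wisp2 at -2.71 ± 0.17 and Wisp1 at -2.60 ± 0.18. Of 12 lipid genes, 3 rose, 2 fell and 7 did not pass (6 up and 2 down adjusted over the list alone), with Apod, a lipid carrier, at 1.30 ± 0.20. All of these values are log2 fold changes ± SE. In total 991 genes were higher and 1129 lower of 11921 tested, or 1592 and 777 with scaling by total UMIs, which shifts the median of all genes by 0.107 (log2) and the share of calls that are higher from 46.7% to 67.2%. The numbers higher and lower were 601 and 714 without WT pool 1, 642 and 789 without WT pool 2, 600 and 651 without KO pool 1, and 634 and 662 without KO pool 2.

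Within the alveolar-like class, the growth factor Igf1, the elastic fiber gene Mfap5 and most collagens fell. The WT cells came mostly from a cluster of 1895 WT and 53 KO cells and the KO cells from one led by C6 and Lcn2 with 33 WT and 875 KO cells. Of 11 alveolar markers 4 rose and 1 fell (4 and 3 adjusted over the list alone; median log2 ratio 0.51), of 10 inflammatory markers 4 rose and 1 fell (1.01), and of 9 fibrotic markers 1 rose and 5 fell (-2.10), both also over the list alone. Igf1 fell from 1109 ± 331 to 75.2 ± 8.48 CPM, a log2 fold change of -4.00 ± 0.23, and Mfap5 fell from 1708 ± 533 to 117 ± 6.41 CPM, a log2 fold change of -3.98 ± 0.22. Ctgf fell from 392 ± 35.6 to 25.2 ± 4.06 CPM, a log2 fold change of -4.09 ± 0.14. Nnat, a neuronatin, had -4.81 ± 0.62, and Igfbp2 fell from 72.5 ± 57.4 to 0.608 ± 0.254 CPM. Cxcl13 rose from 10.1 ± 10.6 to 1172 ± 538 CPM, a log2 fold change of 6.70 ± 0.69. Sema3a rose from 5.59 ± 2.44 to 123.1 ± 39.9 CPM, a log2 fold change of 4.35 ± 0.30, and Ces1f, a carboxylesterase, from 2.02 ± 0.746 to 54.8 ± 23.1 CPM, a log2 fold change of 4.68 ± 0.34. Retnlb, another resistin-like protein, rose from 4.08 ± 6.97 to 151 ± 42.8 CPM, a log2 fold change of 5.02 ± 0.81 (10.59 without WT pool 3 and 12.38 with another clustering seed), and this call was lost with DESeq2 (adjusted p = 0.0771, range over the alternatives 7.02e-211 to 0.0771). Lcn2 rose from 169 ± 196 to 1411 ± 395 CPM, a log2 fold change of 2.92 ± 0.72 (4.55 without WT pool 3), a call lost without WT pool 1, KO pool 1 or KO pool 2 (edgeR Benjamini-Hochberg adjusted p in a range of 2.94e-110 to 0.0838 over the alternatives). The highest adjusted p of the other 8 genes was 0.00122 for Igfbp2 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. They too had been chosen among genes whose pools did not overlap.

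Of 16 TGF-beta response genes in the alveolar-like class, 1 rose, 11 fell and 4 did not pass, with the same numbers adjusted over the list alone and Ltbp2 at -3.67 ± 0.19. Of 19 collagens, 1 rose, 16 fell and 2 did not pass, also over the list alone, with Col12a1 at -2.35 ± 0.10 and Col15a1 at -2.82 ± 0.24. Of 23 other matrix genes, 0 rose, 15 fell and 8 did not pass (1 up and 15 down adjusted over the list alone), with Cilp at -4.35 ± 0.48 (-6.68 without KO pool 2). Of 14 contractile genes, 1 rose, 10 fell and 3 did not pass (1 up and 11 down adjusted over the list alone), with Tagln at -1.70 ± 0.21 and Myl9 at -1.72 ± 0.29. Of 21 chemokines and cytokines, 6 rose, 6 fell and 9 did not pass (6 up and 7 down adjusted over the list alone). Of 18 Wnt pathway genes, 4 rose, 8 fell and 6 did not pass (6 up and 9 down adjusted over the list alone), with Wisp2 at -3.39 ± 0.23 and Dkk2 at -3.92 ± 0.60. Of 13 lipid genes, 7 rose, 2 fell and 4 did not pass, also over the list alone, with Lpl at -2.23 ± 0.25. Fabp4, a fatty acid carrier, had 1.89 ± 0.46 in the adventitial-like and 2.61 ± 0.50 in the alveolar-like class, calls lost without KO pool 2 in both, and 3.06 in the adventitial-like class without WT pool 3. Of 17 early response and dissociation genes 0 rose and 15 fell (16 adjusted over the list alone), against 8 of 17 that fell in the adventitial-like class. Of 16 antigen presentation genes 0 rose and 12 fell, also over the list alone, against 4 of 16 that fell in the adventitial-like class. In total 1158 genes were higher and 1354 lower of 12109 tested, or 1920 and 950 with scaling by total UMIs, which shifts the median of all genes by 0.122 (log2) and the share of calls that are higher from 46.1% to 66.9%. The numbers higher and lower were 618 and 813 without WT pool 1, 620 and 822 without WT pool 2, 482 and 660 without KO pool 1, and 520 and 729 without KO pool 2.

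**Figure D3:**
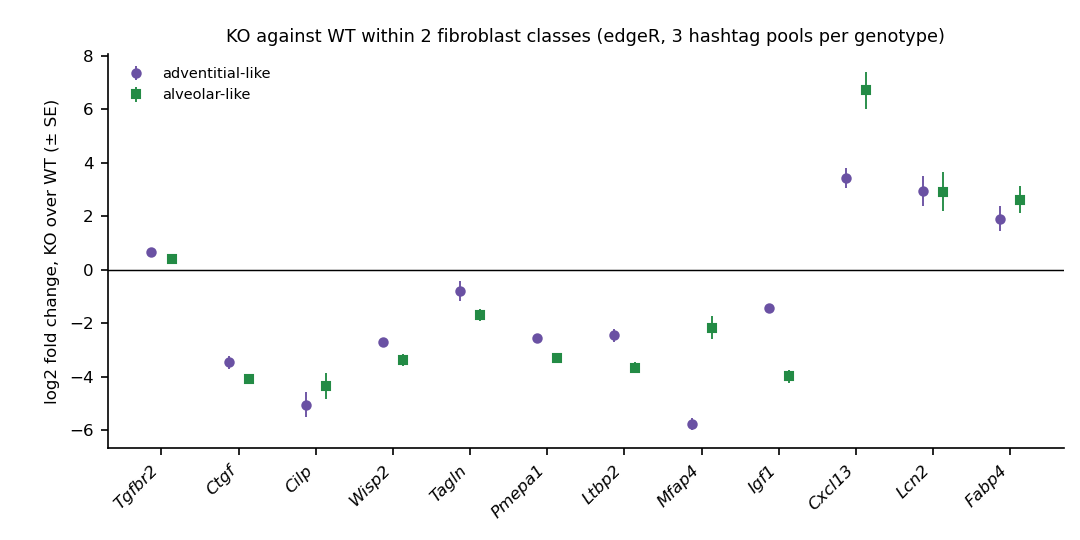
Log2 fold change of KO over WT, with its SE, of 12 genes in the adventitial-like and the alveolar-like class, 3 pools per genotype in each. Ctgf stood at -3.47 and -4.09, Mfap4 at -5.78 and -2.17, and Tgfbr2 at 0.67 and 0.40.

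The difference between the KO effects of both classes was tested in one model. Of 12637 genes, 396 had a more positive and 516 a more negative effect in the alveolar-like class. The positive and negative counts were 237 and 353 without WT pool 1, 263 and 440 without WT pool 2, 209 and 305 without KO pool 1, and 221 and 295 without KO pool 2. Igf1 fell more in the alveolar-like class, with a difference in log2 fold change of -2.53 ± 0.17, and Mfap4 fell more in the adventitial-like class, with 3.35 ± 0.37 (adjusted p of edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment 2.32e-06 and 0.000143). Igf1 and Mfap4 had each been named for a low log2 ratio in the class where it fell more, which favours such a difference. For Ctgf the difference of -0.64 ± 0.28 did not pass the test.

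The proliferating class had WT pools of 32, 26 and 72 cells and was therefore described by library sums without a test, with 95% Poisson intervals. Igf1 had 541 CPM (516 to 566) in WT and 14.5 CPM (12.3 to 16.98) in KO. Eln had 1184 CPM (1147 to 1222) in WT and 51.4 CPM (47.2 to 55.9) in KO, and Postn 659.6 CPM (632 to 688) in WT and 28.7 CPM (25.6 to 32.1) in KO. Ctgf had 693 CPM (665 to 722) in WT and 31.6 CPM (28.4 to 35.2) in KO, and Mfap4 238.2 CPM (222 to 255) in WT and 8.23 CPM (6.61 to 10.1) in KO. Cck had 10.03 CPM (6.90 to 14.1) in WT and 1558 CPM (1534 to 1582) in KO, and Sema3a 19.7 CPM (15.2 to 25.2) in WT and 469 CPM (456 to 482) in KO. Nrn1, Cxcl13 and Slc14a1 were near the detection limit in WT and stood at 329, 141 and 122 CPM in KO. The median log2 ratios were -1.52 for the TGF-beta response list, -1.95 for the collagens, -1.03 for the other matrix genes, 0.92 for the chemokines and cytokines, 0.56 for the glycolysis genes and -0.21 for the proliferation genes.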

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

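The tests in this part, of the difference between the KO effects in the alveolar-like and the adventitial-like class, were chosen only after the class comparisons had been seen. For 14 of the genes named within a class, the KO effect differed between the classes in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 12637 genes. Each value is the log2 fold change of KO over WT in the alveolar-like class minus that in the adventitial-like class, ± SE. The WT and the KO cells of each class come mostly from different clusters, so the differences also hold how those clusters differ.

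Mfap4 fell in the adventitial-like class, 1505 ± 388 to 29.1 ± 4.596 CPM, and the difference was 3.35 ± 0.37 (adjusted p = 0.000143). Cxcl13 rose in both classes and more in the alveolar-like class, by 3.37 ± 0.33 (adjusted p = 5.15e-05). Sema3a differed by 1.98 ± 0.22 (adjusted p = 0.000147) and Ces1f by 2.995 ± 0.42 (adjusted p = 0.000924), both with the higher fold change in the alveolar-like class.

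The other 10 differences were negative. Bpifa2 had -3.57 ± 0.39 (adjusted p = 0.000145) and Slco2a1 -3.36 ± 0.20 (adjusted p = 2.23e-06), both genes that rose in the adventitial-like class. Ifitm1 had -0.49 ± 0.14 (adjusted p = 0.0478). Igf1 had -2.53 ± 0.17 (adjusted p = 2.32e-06), Mfap5 -1.62 ± 0.24 (adjusted p = 0.00129), and Pmepa1 -0.75 ± 0.12 (adjusted p = 0.00189). Igfbp2 had -5.49 ± 0.63 (adjusted p = 0.000197) and Nnat -4.07 ± 0.56 (adjusted p = 0.000681), both genes that fell in the alveolar-like class. Ltbp2 had -1.10 ± 0.25 (adjusted p = 0.0184) and Lpl -1.42 ± 0.17 (adjusted p = 0.000279). The 10 splits of the 6 pools are too few for a share under 0.05: 1 split, the real one, called 912 genes, and the highest of the others called 0. Every other split mixed WT and KO pools on both sides, so the difference between the libraries added to the spread within its groups. Their calls of 0 are therefore no further support.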

How the results depend on the processing

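The tests between pools under other gene filters, scalings, DESeq2, a block for the hashtag number and thinned cells were chosen only after the data had been seen. So were the removal of the highest Scrublet scores, the other clustering seeds and all alternatives of the class tests. Over 57 results, 447 values under alternatives stayed within their limits, 72 moved and 1 reversed. Of 160 named gene results, 134 kept their direction and their side of the threshold under every alternative run and 26 changed under at least 1, as 79 lost and 6 gained calls. Of the 40 counts of list members called, 729 values stayed within 1.5 times and 71 moved, 51 of them with 1 pool left out and 6 with the block, most often counts of 3 or fewer. Scrublet removed no cell used, so that alternative is void. For the results that follow the cause was not tested, except that left-out pools and thinning leave fewer mice or UMIs.

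With the classes weighted equally, 125 genes were 2-fold higher and 179 lower, the log2 ratio of Tgfbr2 was 0.20, and the median log2 ratios were -0.95 for the TGF-beta response, -0.11 for TGF-beta ligands and receptors, -1.06 for collagens, -1.29 for other matrix genes and 0.00938 for proliferation. The median was 0.39 for glycolysis, -0.17 for the Wnt pathway and -0.18 for complement. This weighting covers only the adventitial-like, alveolar-like and proliferating classes, without the fibrotic-like and unnamed clusters. The log2 ratio of Tgfbr2 was 0.10 as a mean over cells and 0.10 with thinned cells. Growth factors at 20 CPM or more had a median of 0.38. The BMP response was -0.11 without WT pool 3.

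The alveolar-like share of WT cells was 11.9% at resolution 1.2 and 22.0% with the filter of 500 genes and 20% mitochondrial UMIs, and that of KO cells 1.64% at resolution 0.4. With the 500-gene filter the fibrotic-like share of WT was 29.1% and the unnamed shares 9.34% of WT and 48.0% of KO. The unnamed share of WT was 38.2% at resolution 1.2, and that of KO 63.0% at resolution 0.4, 37.0% at resolution 1.2 and 35.7% in clusters made without the TGF-beta and matrix lists.

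Differences in the share of cells with a UMI (KO minus WT, in points) without thinning were -18.8 for Cthrc1, -35.0 for Postn, -3.59 for Lrrc15, -19.5 for Pi16, -1.10 for Dpt, 25.6 for Saa3, 30.5 for Lcn2 and 6.40 for Mki67. Thinned to 1500 UMIs they were -11.6 for Cthrc1, -18.5 for Postn, -0.880 for Lrrc15, 0.0130 for Dpt, 17.2 for Saa3 and 17.3 for Lcn2. With at least 2 UMIs they were -10.4 for Cthrc1, -17.3 for Postn, -0.344 for Lrrc15, -10.6 for Pi16, 0 for Dpt, 15.8 for Saa3 and 14.998 for Lcn2.

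Of called genes, 1888 were higher over all fibroblasts with thinned cells. Scaling by total UMIs gave 1592 higher genes in the adventitial-like and 1920 in the alveolar-like class, and no gene filter gave 946 more negative in the alveolar-like class. Leaving out 1 pool gave 1836 to 3621 higher genes over all fibroblasts, 600 to 1252 higher and 651 to 1415 lower in the adventitial-like class, and 482 to 1589 higher and 660 to 1683 lower in the alveolar-like class. It gave 559 to 982 higher in the cluster led by Myh11, and 209 to 397 more positive and 295 to 609 more negative effects in the alveolar-like class. The TGF-beta response then had medians of -0.80 to -0.62 and the BMP response of -0.11 to 0.14. The secretory pathway had 0.0676 without KO pool 2.

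With the hashtag number as a replicate block, 707 genes were higher in the alveolar-like class, and the other counts of called genes stayed within 1.5 times. Deviations of same-numbered pools had correlations of -0.04, -0.20 and -0.26, so the numbers give no pairing. Depth limits genes near the detection limit and the classes with few cells per pool.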

Other observations

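The tests of depth and of other splits in this part were chosen only after the result was seen, as was the comparison within the cluster led by Myh11. That cluster held 502 WT and 430 KO cells at resolution 0.4, with 6 of 7 smooth muscle markers raised, 4 of them among its 10 leading genes, and 5 peribronchial markers raised, and stayed unnamed because both types were close. At resolution 0.8 it came apart by library, with 463 of its WT and 7 of its KO cells in a cluster led by Myh11 and 2 WT and 417 KO cells in another led by Adamdec1 and Igfbp3. The comparison thus sets cells of separate clusters side by side, and its differences also hold how those differ. Over the cells together the tendon regulator Scx fell from 325 ± 93.4 to 6.74 ± 0.701 CPM, a log2 fold change of -5.60 ± 0.28. Postn fell from 1467 ± 125 to 41.7 ± 29.0 CPM, a log2 fold change of -5.12 ± 0.38, and Cnn1, a smooth muscle protein, from 355 ± 126 to 26.6 ± 14.0 CPM, a log2 fold change of -3.76 ± 0.35. Stc1 rose from 18.6 ± 11.4 to 749 ± 209 CPM, a log2 fold change of 5.38 ± 0.32, and Saa3 from 45.8 ± 66.9 to 1321 ± 364 CPM, a log2 fold change of 4.80 ± 0.81 (7.70 without WT pool 3, which stood at 122.9 CPM against 11.3 and 3.21 in WT pools 1 and 2). Markers of cell types moved as well: 5 of 7 smooth muscle (median log2 ratio -1.36), 5 of 6 peribronchial (-1.82) and 8 of 10 fibrotic markers (-2.94) fell and 0 rose, and 7 of 9 inflammatory markers rose and 0 fell (1.77). Adjusted over the list alone, 6 peribronchial markers fell and 9 inflammatory markers rose. Of 15 contractile genes 0 rose and 12 fell, and of 7 complement genes 7 rose and 0 fell, both the same adjusted over the list alone. Of 15 TGF-beta response genes 1 rose and 11 fell, of 17 collagens 0 rose and 12 fell, both also over the list alone, and of 16 chemokines and cytokines 9 rose and 1 fell (13 and 1 adjusted over the list alone). In edgeR's quasi-likelihood test 873 genes were higher and 921 lower of 9096 tested, with 559 higher without WT pool 2. Tgfbr2 was 217 ± 21.6 to 340 ± 24.6 CPM from WT to KO (log2 fold change 0.59 ± 0.12).

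Several unnamed clusters held KO cells almost alone. One led by Retnla and Tnfsf11 held 1 WT and 1593 KO cells, and one led by Nppc, Il1rl1, Cck and Ccl2 held 2 and 1201. With 1 library per genotype, such a cluster cannot be told from its library. Dpt (chromosome 1, 164796663 to 164824274 in GRCm38), named in the series title, had 1.32 ± 0.217 CPM in WT and 0.503 ± 0.196 in KO. It was fixed in advance as an adventitial marker and for its share of cells, but its level was looked at after its values were seen. At these low levels its log2 fold change ran from -1.73 to -1.18 over the fits run. Adjusted p (edgeR's test or DESeq2, Benjamini-Hochberg adjustment) ran from 0.00394 to 0.0447.

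The KO against WT differences over all fibroblasts may come from the genotype or from the separate 10x channels. A shared channel effect would also move other cells. In 35 WT and 64 KO non-fibroblast and pericyte cells, 409 of the called genes had a median log2 ratio, signed by the fibroblast direction, of 0.63. Its 95% bootstrap interval, taken over genes and not over cells, was 0.55 to 0.71, against a median of 1.18 in fibroblasts. The bound for excluding a channel effect, 0.59, lies inside that interval, so the channel stays open, as does free RNA from fibroblasts. These cells were sorted as YFP-positive too and may have lost Tgfbr2, so the genotype could move them as well. The test thus cannot tell channel from genotype. Lower depth of the KO cells was examined by turning it round. The 2812 WT fibroblasts under the WT median of UMIs were set against the 3344 KO fibroblasts over the KO median. With medians of 8677 and 11979 UMIs, the KO cells are the deeper ones there. Over all 2104 genes called at least 2-fold, the median signed log2 ratio of library sums was 0.86 (95% bootstrap interval over genes 0.81 to 0.90). It was 0.72 over all fibroblasts, so the differences did not turn with depth. However, the genes and their directions came from these same cells. Splitting by UMIs also changes the mix of clusters, whose median UMIs ran from 6625 (led by Cxcl13) to 16834 (proliferating). The comparison therefore cannot separate depth from cluster mix. Depth also stays open for single genes near the detection limit, with 573 genes called higher and 791 lower by at least 2-fold when every cell is thinned to 3000 UMIs. The 10 splits of the 6 pools are too few for a share under 0.05: 1 split, the real one, called as many genes in each comparison, 6032 over all fibroblasts, 2120 in the adventitial-like class, 2512 in the alveolar-like class and 1794 in the cluster led by Myh11, and the highest of the others called 0. As every other split mixed WT and KO pools on both sides, the difference between the libraries added to the spread within its groups. Those calls of 0 give no further support.

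A few KO cells lay in clusters made mostly of WT cells. Barcodes carried over from the WT library are argued against, since 1 of these 172 KO cells (0.581%, exact 95% interval 0.0147 to 3.197) had a barcode also found in WT, against 10 of 6516 other KO fibroblasts (0.153%). In clusters made without the TGF-beta and matrix lists, 204 such KO cells had a median log2 ratio of the 16 TGF-beta response genes of -0.0621 against 4656 WT cells of the same clusters, where 6487 other KO fibroblasts had -0.80 against all WT fibroblasts. The 95% bootstrap interval of the former, -0.37 to 0.18, was taken over genes and holds no spread between cells or mice. Ctgf stood at 491 CPM in these KO cells, 527 CPM in WT cells of the same clusters and 17.9 CPM in the other KO fibroblasts. Tgfbr2 stood at 529 CPM in these KO cells, 472 CPM in those WT cells and 418 CPM in the other KO fibroblasts. Its level does not check the receptor, since the assay need not count the deleted part. A candidate explanation is that these cells kept a working TGF-beta receptor, though they were chosen for lying among WT cells, and all 3 KO hashtags occurred among them, in 86, 64 and 42 cells.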
